A study of Mus musculus with 8 samples.

How the data were processed

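RNA was measured in astrocytes that had been flow sorted from cortical and subcortical tissue of 4 wild-type mice at postnatal day 29. Per the labels' protocols, thawed lysates were extracted with the RNeasy Plus Micro kit and made into libraries with the forward QuantSeq 3′ mRNA-Seq kit of Lexogen, which primes at the poly(A) tail and so counts about 1 fragment per transcript end, without a bias for long transcripts. The gate or reporter used for sorting is not given in the sources used here. The submitters' processing notes name FastQC 0.11.5, STAR 2.6.0, HTSeq 0.9.0 and DESeq2 1.35.0 and the build GRCm39, without settings. Whether molecular identifiers or strand were used in counting is not given in the sources used here, so genes with overlapping, antisense or near-identical copies are uncertain.

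The authors deposited whole-number counts per gene, 1 table per sample, which were used as deposited. Each holds 55417 gene rows and 5 closing HTSeq summary rows. The summary rows stayed out of library sizes and tests. Reads that HTSeq assigned to no feature were 30.2 to 40.7% of the gene, ambiguous and no-feature total of a library. Ambiguous reads were 0.38 to 0.55%. A table of normalized values for the whole series was not used here. Symbols were matched by gene identifier for 52083 of the 55417 rows. No coordinates are given, since the annotation at hand is of another build. Levels are given as CPM on library sizes scaled by trimmed means of M-values (TMM), so that a CPM refers to effective rather than raw library totals. A fold against a region without counts was set against a floor of 3 counts over the group, and where 1 to 3 counts were found the ratio has an exact binomial interval at 95%. A count of 0 in a library allows 0.70 to 1.44 CPM. Intervals and floors cover counting error only.

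Samples were grouped by the region, sex and mouse number in their titles. The main test of region was edgeR 4.0.16 (R 4.3.3) with filterByExpr (10 counts in at least 4 libraries, scaled for size, and 15 in total), TMM factors, estimated dispersions and quasi-likelihood tests, 4 libraries against 4, with Benjamini-Hochberg adjustment at 0.05. Directions are cortical minus subcortical and female minus male. Sex and the interaction were tested in 1 fit with a mean for each sex and region (2 libraries each), and sex over both regions on counts summed per mouse (2 mice against 2). Lists of genes were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 tested members, and again with a correlation estimated per list. Single library measures were compared with exact permutation tests that exchanged libraries freely, without regard to the pairing by mouse.

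The model, the 34 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The named genes are those with an adjusted p under 0.05, a mean of at least 10 CPM, the same direction in all 4 mice and a symbol that is not of a predicted, RIKEN or pseudogene kind, taking the 12 with the largest log2 fold change per direction; for sex and the interaction the 5 per direction with the smallest adjusted p; all adrenergic receptor and X and Y linked list members; and up to 4 members of each other list with the smallest p. A few of the genes so chosen are not reported here. The alternatives were DESeq2-type size factors in edgeR, DESeq2 1.42.0, limma-voom, no and a stricter (5 CPM) low-count filter, and TMM factors without mitochondrial and other-cell genes. Others were sex as a covariate, the mouse as a block, an adjusted p under 0.01 and a test against a fold of 1.5. Region was also tested in each sex as a contrast of the fit by sex and region. Each library or mouse was left out in turn, and the mouse was taken as a random effect. For lists the alternatives were a correlation estimated per list and lists without members that a marker list of another cell type also holds. Thinning all libraries to the smallest total, leaving marker genes of other cells out of the count and leaving single libraries out of the list tests were added after the data were seen.

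The mouse numbers of the titles pair the samples, since the cortical and subcortical sample with the same number came from the same animal. As a check, deviations from the region means correlated at 0.0195 to 0.0592 over genes between samples of the same mouse. Between samples of different mice in different regions they correlated at -0.0841 to 0.0471. The pairing was thus weak over all genes together, which does not settle it for single genes. With the mouse as a block 885 genes were called by region, among them 770 of the 802 of the main test. The block also gave 15 called lists in place of 13. Libraries of 1 region correlated at 0.866 to 0.900 and differed by more than sampling noise (chi-square per degree of freedom 11.7 to 23.7), so each counted as 1 replicate. The samples of a group are different animals. In data simulated from the real means, 200 genes with a mean of at least 10 CPM were changed. Among 11379 genes the region test found 41% of the 2-fold and 88% of the 4-fold changes, with 6.5% of its calls false. Sex summed per mouse gave 36% and 88% over 11751 genes. In the simulated gene lists, the changed list, made of genes that had been shifted, was called and 0 of 20 random lists were. The simulated genes varied independently of each other, so this does not test false calls for lists with correlated members.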

Results

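Gene counts from 8 libraries of flow-sorted astrocytes were compared between brain regions and between the sexes. Astrocytes are the glial cells that take up neurotransmitters, buffer potassium and contact synapses and blood vessels. The cells came from 4 wild-type mice at postnatal day 29, 2 females and 2 males, and each mouse gave a cortical and a subcortical sample, so that each region had 4 libraries and each sex 2 libraries per region. The libraries read the 3′ ends of polyadenylated transcripts. Gene counts summed to 3.82 ± 0.27 M per cortical library (SD, n = 4, range 3.54 to 4.06) and to 2.94 ± 0.60 M per subcortical library (SD, n = 4, range 2.48 to 3.83), a difference that did not pass an exact two-sided permutation test (p = 0.0857, smallest possible 0.0286). Mitochondrial transcripts took 10.1 ± 0.99% of cortical and 11.9 ± 1.90% of subcortical counts (SD, n = 4, exact permutation p = 0.171), and the 10 most abundant genes took 20.8 ± 1.80% and 31.4 ± 5.17%. A tdTomato reporter feature had 0 counts in all 8 libraries. Over the tested genes, the first principal component held 30.2% of the variance and separated the regions.

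The first comparison asked how cortical astrocytes differ from subcortical ones. Transcription factors that pattern the telencephalon marked the cortical cells, and those that pattern the diencephalon and midbrain marked the subcortical cells. Lhx2 (ENSMUSG00000000247), a LIM homeobox factor of forebrain development, stood at 327.5 ± 14.8 CPM in cortical and 3.08 ± 1.80 CPM in subcortical libraries (SD, n = 4). Irx3, an Iroquois homeobox factor, went the other way, with 7.18 ± 2.34 CPM in cortical and 162.4 ± 29.8 CPM in subcortical libraries (SD, n = 4). The glutamate transporter gene Slc1a3 was 2.4-fold higher and the GABA transporter gene Slc6a11 4.7-fold lower in cortical cells, while genes for uptake and metabolism of these transmitters were not called as a set. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 802 of 11781 tested genes passed an adjusted p of 0.05, 403 higher and 399 lower in cortical cells. Of these, 780 moved the same way in all 4 mice, 542 differed by more than 2-fold and 194 by more than 4-fold. Tested against a fold of 1.5 the count was 333.

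The genes with the largest rises in cortical cells included developmental regulators, signalling modulators and genes known from neurons. Besides Lhx2 (log2 fold change 6.62, SE 0.28, edgeR adjusted p = 1.1e-12) they held, from the zinc finger and DM domain families of transcription factors, Fezf2 (6.23, SE 0.55) and Dmrta2 (4.62, SE 0.29). Crym, which encodes a thyroid hormone-binding crystallin, had a log2 fold change of 6.60 (SE 0.41), and Chrdl1, which encodes a secreted antagonist of bone morphogenetic proteins, one of 5.27 (SE 0.35). Lypd6 and Prom1, whose product is the membrane protein prominin 1, had 2 counts each over the 4 subcortical libraries. Their count ratios, scaled for library size, were 171 (95% counting interval 47.1 to 1416.5) and 154 (42.5 to 1278). Nrgn, a postsynaptic calmodulin-binding protein gene of neurons, stood at 195.8 ± 77.4 against 8.73 ± 2.56 CPM (SD, n = 4). Dact2 and Fam13c had log2 fold changes of 4.36 and 4.31.

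Among the largest falls in cortical cells, Pax3, a paired box factor, had 1 count over the 4 cortical libraries and 28.9 ± 12.8 CPM (SD, n = 4) in subcortical ones, a count ratio of 446 (95% counting interval 79.4 to 17661). Irx5 and Irx1 accompanied Irx3, with log2 fold changes of -4.45 (SE 0.62) and -4.14 (SE 0.45), and the forebrain and midbrain factors Foxb1 and Otx2 followed with -4.11 (SE 0.25) and -3.45 (SE 0.45). Cyp26b1, whose product degrades retinoic acid, fell from 120.3 ± 43.6 CPM in subcortical to 2.71 ± 2.11 CPM in cortical libraries (SD, n = 4). Dao, the D-amino acid oxidase gene, had a log2 fold change of -5.14 (SE 0.61). Acvr1c, an activin-type receptor gene, Gjc3, a connexin gene, Car10 and Thbs2, which encodes a secreted thrombospondin, had log2 fold changes between -3.35 and -3.00. All of these genes moved the same way in all 4 mice, which was part of the rule that chose them.

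**Figure D1:**
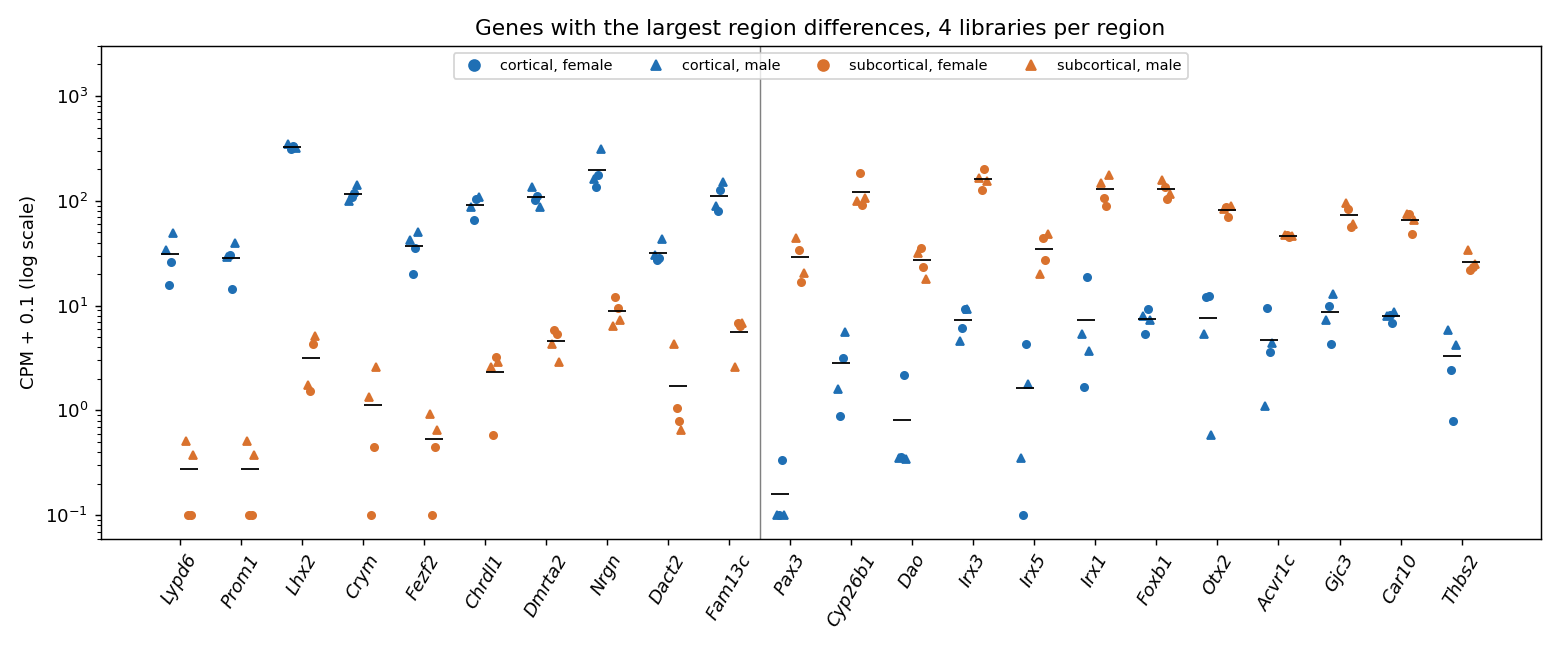
CPM plus 0.1 on a log scale for 10 of the genes with the largest rise (left of the line) and the 12 with the largest fall (right) in cortical astrocytes. Points are single libraries (4 per region, circles female, triangles male) and bars are means of 4; Lhx2 averaged 327.5 CPM in cortical and 3.08 CPM in subcortical libraries.

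Gene lists that had been fixed in advance ordered these differences. Of 8 tested dorsal telencephalic transcription factors, 7 rose in cortical cells and 1 was not called, and all 8 rose when adjusted over the list alone. Of 19 tested diencephalic, midbrain and ventral forebrain transcription factors, 12 fell, 3 rose and 4 were not called, with the same counts adjusted over the list alone. The list of telencephalic grey matter astrocyte markers had 7 of 14 members higher, 4 lower and 3 not called, the same adjusted over the list alone, with 2 lower without cortical 3 or subcortical 1. Its members included Dio2, which encodes the deiodinase that activates thyroid hormone, at 1152.9 ± 226.1 against 229.3 ± 34.9 CPM, and Mfge8, a secreted bridging protein gene in phagocytosis, at 7378 ± 1505 against 1793 ± 401 CPM (SD, n = 4). Non-telencephalic astrocyte markers had 7 of 11 members lower, 1 higher and 3 not called (8 lower and 1 higher adjusted over the list alone). Slc6a11 stood at 10944 ± 1703 CPM in cortical and 51513 ± 11697 CPM in subcortical libraries (SD, n = 4), the glycine transporter gene Slc6a9 had a log2 fold change of -2.19 (SE 0.16) and the angiotensinogen gene Agt one of -1.92 (SE 0.18). Hopx, a homeodomain-only protein gene on the same list, went the other way with a log2 fold change of 3.83 (SE 0.28). By limma's camera test these 4 lists moved as sets, with adjusted p of 1.4e-49, 6.8e-17, 1.8e-12 and 1.7e-11. These calls held with a correlation estimated per list, with adjusted p = 0.00014, 0.0053, 0.0090 and 0.0090.

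**Figure D2:**
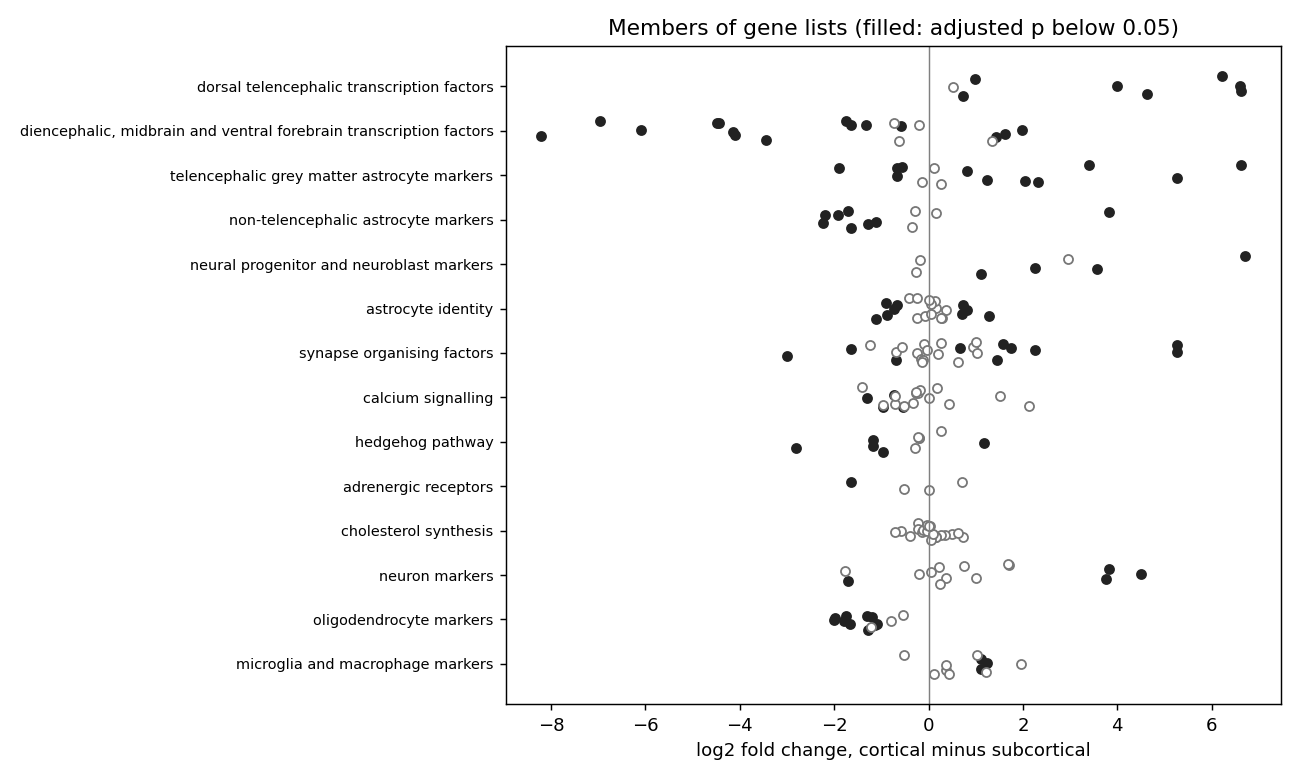
Log2 fold change (cortical minus subcortical) of each tested member of 14 gene lists; each point is a gene, filled where the edgeR adjusted p was under 0.05. The dorsal telencephalic transcription factors lie to the right, with 7 of 8 called higher, and oligodendrocyte markers to the left, with 10 of 13 called lower.

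Neural progenitor and neuroblast markers also moved as a set (camera adjusted p = 3.1e-06; with an estimated correlation, adjusted p = 0.014), with 4 of 7 higher, 3 not called and 0 lower (5 higher adjusted over the list alone). Ccnd2, a D-type cyclin gene, stood at 365.2 ± 51.1 against 75.9 ± 9.8 CPM and Sox11 at 81.4 ± 15.4 against 37.4 ± 11.2 CPM (SD, n = 4). Top2a, a gene of dividing cells, had a log2 fold change of 3.57 (SE 0.95, edgeR adjusted p = 0.022). With the mouse as a block its adjusted p was 0.058, with limma-voom 0.154, and it also missed the threshold without cortical 2 or 3 or subcortical 2, 3 or 4, where the adjusted p lay between 0.051 and 0.129.

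Genes that all astrocytes express differed in both directions. Of 21 astrocyte identity genes, 4 rose, 5 fell and 12 were not called (4 and 6 adjusted over the list alone), and the list did not move as a set (camera adjusted p = 0.952, direction down, median log2 fold change 0.045). Slc1a3 stood at 5815 ± 617 against 2408 ± 305 CPM and Slc1a2, the other main astrocytic glutamate transporter gene, at 9707 ± 707 against 5522 ± 244 CPM, whereas Aqp4, the water channel gene, stood at 483 ± 93 against 1047 ± 212 CPM (SD, n = 4). Potassium and water transport genes had 1 of 17 higher and 7 lower (2 and 7 adjusted over the list alone; camera adjusted p = 0.317), among them Kcnj10, a potassium channel gene, with a log2 fold change of -1.61 (SE 0.17), against Atp1b1, a sodium pump subunit gene, with 3.76 (SE 0.18). Glutamate and GABA uptake and metabolism had 3 of 17 higher and 5 lower (4 and 6 adjusted over the list alone). As a set it missed the threshold (camera adjusted p = 0.055) and with an estimated correlation (0.203), and passed it with the mouse as a block (0.031). Without cortical 1 or subcortical 2, 3 or 4 the adjusted p was 0.018, 0.029, 0.018 and 0.041. Neurotransmitter receptors had 3 of 22 higher and 5 lower (3 and 8 adjusted over the list alone), with camera adjusted p = 0.068, 0.158 with an estimated correlation, 0.047 with the block, and 0.034 and 0.044 without subcortical 2 or 4. The AMPA receptor gene Gria1 stood at 158.8 ± 29.4 against 600.2 ± 94.8 CPM and the NMDA receptor gene Grin2c at 535.6 ± 55.2 against 204.6 ± 27.9 CPM (SD, n = 4).

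Synapse organising factors had 7 of 25 members higher, 3 lower and 15 not called (8 and 3 adjusted over the list alone). Mertk, a phagocytic receptor gene, stood at 744.4 ± 37.9 against 221.6 ± 41.0 CPM and Sparc, a secreted matrix protein gene, at 1301 ± 312 against 4033 ± 259 CPM (SD, n = 4). The list moved up by camera (adjusted p = 0.0049), but not with an estimated correlation (adjusted p = 0.108). The hedgehog pathway had 4 of 10 lower and 1 higher, the same adjusted over the list alone, and moved down (camera adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.108). Ptch1 and Gli1, which hedgehog signalling induces, stood at 288.8 ± 34.8 against 655.1 ± 77.0 CPM and 57.3 ± 6.3 against 130.3 ± 34.7 CPM, and Gli3, which encodes a factor that also acts as a repressor, at 85.2 ± 10.9 against 37.5 ± 12.3 CPM (SD, n = 4). Calcium signalling genes had 4 of 19 lower and 0 higher (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.021), with no call under an estimated correlation (adjusted p = 0.108). The count of 4 fell to 1 without cortical 3 and to 2 without cortical 1, cortical 2 or subcortical 4. The phospholipase gene Plcb4 had a log2 fold change of -1.29 (SE 0.26) and was called without any single library. The others, Camk2d, Atp2b4 and Atp2a2, each lost their call without cortical 3, subcortical 4 and 2 further libraries, which were cortical 2 and subcortical 2, cortical 1 and 2, and cortical 1 and subcortical 1 (edgeR adjusted p of 0.053 to 0.142). Immediate early and dissociation genes had 1 of 12 higher (2 adjusted over the list alone), the transcription factor gene Jun at 78.1 ± 16.7 against 39.97 ± 7.04 CPM (SD, n = 4). With the mouse as a block, or without subcortical 3, 2 of these genes were higher. Their set moved up (camera adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.217).

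The lists for metabolism, matrix and other pathways were not called as sets. White matter and fibrous astrocyte markers had 5 of 19 higher and 1 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.234, direction up with a median of -0.24). With the mouse as a block 5 were lower. Without single libraries 4 to 7 were higher and 1 to 3 lower, with 7 and 3 without subcortical 2 and 2 lower without cortical 1, cortical 2 or subcortical 4. Extracellular matrix genes had 4 of 25 higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.866, direction up with a median of -0.13), among them Hapln1, a hyaluronan link protein gene, at 132.6 ± 20.4 against 11.9 ± 3.0 CPM (SD, n = 4). The Wnt pathway had 3 of 12 higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.843), with the secreted inhibitor gene Sfrp5 at a log2 fold change of -2.36 (SE 0.21). Without single libraries 2 to 4 were higher and 2 or 3 lower. Glycogen and lactate metabolism had 2 of 23 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.350), with the glycogen-targeting subunit gene Ppp1r3g at 2.33 (SE 0.21). Only 1 was higher with the mouse as a block and without cortical 2 or 3 or subcortical 1, 2 or 3. Astrocyte morphogenesis genes had 3 of 32 higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.467), with the membrane linker gene Ezr at 308.0 ± 36.0 against 46.2 ± 4.8 CPM (SD, n = 4). Without single libraries 1 to 3 were higher (1 without cortical 3 or subcortical 4) and 1 or 2 lower (1 without cortical 1, 2 or 3). BMP pathway targets had 1 of 11 higher and 1 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.317), with Id4 at 1.53 (SE 0.21). The lower count was 2 with the mouse as a block and without subcortical 2, and 0 without cortical 2, 3 or 4 or subcortical 1. Reactive astrocyte genes had 2 of 16 higher and 0 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.454), with Gfap at 39.1 ± 3.8 against 14.3 ± 6.0 CPM (SD, n = 4). The higher count was 3 with the mouse as a block and without subcortical 2, and 1 without subcortical 1 or any cortical library. The lower count was 1 without cortical 1 or subcortical 2. Steroid and thyroid hormone receptors had 1 of 10 higher, also adjusted over the list alone (camera adjusted p = 0.637, direction up with a median of -0.07). That gene, the progesterone receptor gene Pgr, had 164 counts in cortical and 0 in subcortical libraries, at least 36.7-fold higher against a floor of 3 counts over the group. Of 21 cholesterol synthesis genes 0 were called, also adjusted over the list alone (camera adjusted p = 0.752); 1 of them, Mvd, was called with the mouse as a block (adjusted p = 0.037).

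The series concerns β-adrenergic signalling, so adrenergic receptor genes were followed. Adrb1 (ENSMUSG00000035283), the β1 receptor gene, stood at 96.3 ± 7.3 CPM in cortical and 139.0 ± 15.5 CPM in subcortical libraries (SD, n = 4), and was lower in the cortical library of all 4 mice. Its log2 fold change of -0.53 (SE 0.17, 95% interval -0.89 to -0.17) missed the threshold over all genes with edgeR (adjusted p = 0.072) and passed it with DESeq2 (adjusted p = 0.023). Adra2a (ENSMUSG00000033717), the α2A receptor gene, was 3.1-fold lower in cortical cells, at 115.2 ± 26.7 against 361.3 ± 41.5 CPM (SD, n = 4, edgeR adjusted p = 2.0e-06). Adra1b stood at 57.6 ± 17.97 against 35.1 ± 9.3 CPM (SD, n = 4, edgeR adjusted p = 0.149) and Adra1a at 37.1 ± 10.99 against 36.7 ± 6.5 CPM (SD, n = 4, edgeR adjusted p = 0.990). Thus 1 of 4 tested receptor genes was called lower and 0 higher. Adjusted over the list alone, 2 were lower (Adra2a and Adrb1) and 1 higher (Adra1b). As a set they gave a camera adjusted p of 0.057, 0.169 with an estimated correlation and 0.051 with the mouse as a block. Without single libraries it lay between 0.029 (without subcortical 2) and 0.134. Adra2c had 2 counts over all 8 libraries, and Adrb3, Adra1d and Adra2b had 0, so that any expression of these 3 was not detectable at this depth. A count of 0 allows between 0.70 and 1.44 CPM in a single library. Downstream, 2 of 27 cAMP signalling genes fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.866). These were the adenylyl cyclase gene Adcy8, at 7.76 ± 3.14 against 24.2 ± 9.9 CPM, and the phosphodiesterase gene Pde4d, at 14.7 ± 3.2 against 35.3 ± 19.8 CPM (SD, n = 4). Both calls were lost when single libraries were left out. For Adcy8 these were cortical 2 or 3 or subcortical 3 or 4, with adjusted p of 0.055 to 0.078, and for Pde4d 6 of the 8 libraries, with adjusted p of 0.050 to 0.247, and Pde4d was also lost with limma-voom (0.092). Of 4 monoamine handling genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.127). They were Slc22a4, a cation transporter gene, and Maoa, the monoamine oxidase A gene, at 44.2 ± 13.1 against 82.5 ± 3.3 CPM (SD, n = 4). Maoa lost its call without cortical 2 (adjusted p = 0.063) and Slc22a4 without 6 of the 8 libraries (adjusted p of 0.050 to 0.092).

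**Figure D3:**
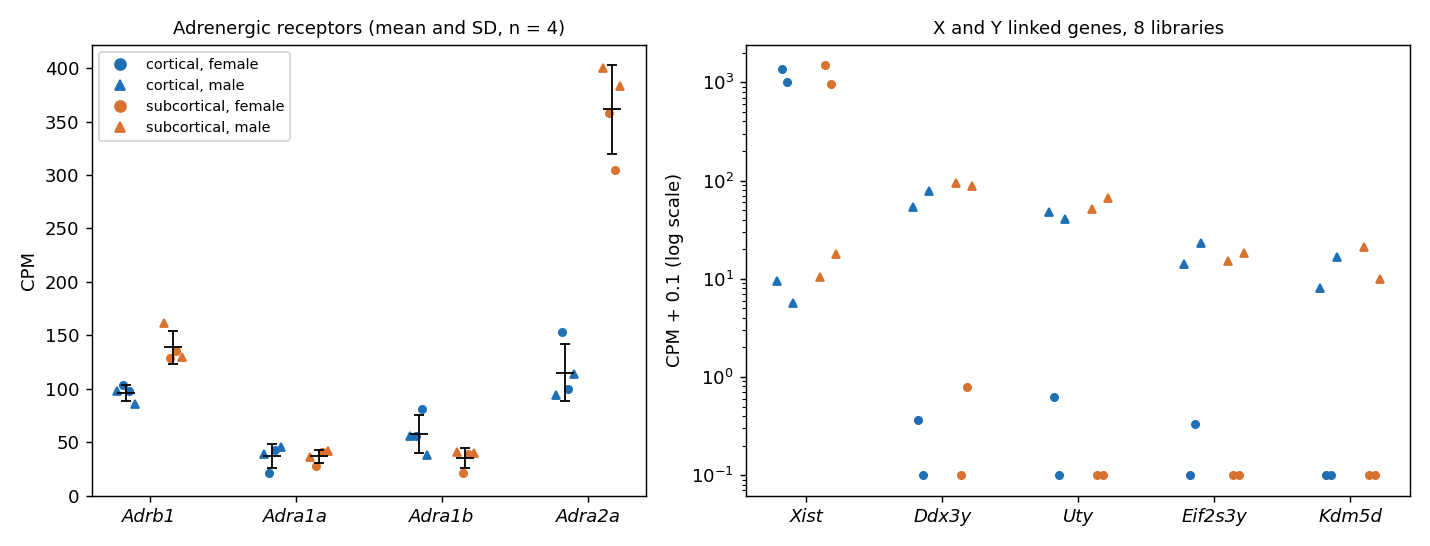
Left, CPM of 4 adrenergic receptor genes per library (circles female, triangles male) with the mean and SD of 4 libraries per region; Adra2a averaged 115.2 CPM in cortical and 361.3 CPM in subcortical libraries. Right, CPM plus 0.1 on a log scale of X and Y linked genes per library; in females the 4 Y-linked genes had 0 to 3 counts each over 4 libraries.

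Markers of other brain cells were measured in the same libraries. Oligodendrocyte markers summed to 1229 ± 243 CPM in cortical and 3793 ± 1606 CPM in subcortical libraries (SD, n = 4). An exact two-sided permutation test that ignored the pairing by mouse gave p = 0.0286, the smallest possible. Of the 13 markers 10 were lower and 0 higher (12 lower adjusted over the list alone). Mog, a myelin surface protein gene, stood at 23.8 ± 9.8 against 80.0 ± 26.6 CPM (SD, n = 4). The list was called down by camera (adjusted p = 5.9e-14), but not with an estimated correlation (adjusted p = 0.090). Oligodendrocyte precursor markers had 3 of 6 lower and 0 higher, the same adjusted over the list alone, with Olig1 at 161.2 ± 40.4 against 340.6 ± 60.6 CPM (SD, n = 4; camera adjusted p = 0.0049; with an estimated correlation, adjusted p = 0.132). Olig2 lost its call without cortical 1 or 3 or subcortical 1 (edgeR adjusted p of 0.068 to 0.105). Enpp6 lost it with the mouse as a block (0.055), with limma-voom (0.063) and without cortical 2 or 3 or any single subcortical library (0.055 to 0.121). Neuron markers had 3 of 14 higher and 1 lower (6 and 2 adjusted over the list alone). Their camera adjusted p was 0.00010, and 0.11 with an estimated correlation. Without single libraries 3 to 5 were higher (5 without cortical 1) and 1 or 2 lower (2 without cortical 4). Nrgn, the kinase gene Camk2a (86.4 ± 70.7 against 5.97 ± 2.37 CPM) and the vesicular glutamate transporter gene Slc17a7 (15.8 ± 11.4 against 1.15 ± 0.90 CPM) were higher, and the neurofilament gene Nefl (12.1 ± 3.7 against 39.9 ± 16.2 CPM) was lower (SD, n = 4). Cortical 4 was the highest library for all 3 risen genes, with Camk2a at 190.0 CPM (other cortical libraries 36.7 to 72.5) and Nrgn at 308.8 CPM (135.3 to 178.0), and without it both calls held, with log2 fold changes of 3.09 and 4.19. The call of Slc17a7 was lost with limma-voom (adjusted p = 0.186). Microglia and macrophage markers had 3 of 11 higher and 0 lower (5 adjusted over the list alone; camera adjusted p = 0.038; with an estimated correlation, adjusted p = 0.493). Without cortical 4 or subcortical 3 the camera adjusted p of the microglia list was 0.216 and 0.126, and its called members Csf1r, C1qa and Cx3cr1 lost their calls without either of these (edgeR adjusted p of 0.112 to 0.230). Each also lost its call without cortical 2 and 2 further libraries (0.055 to 0.148), among cortical 1 and subcortical 4 for C1qa, cortical 3 and subcortical 1 for Csf1r, and cortical 1 and subcortical 1 for Cx3cr1. With limma-voom Csf1r and Cx3cr1 were lost too (0.057 and 0.063). Ependymal and choroid plexus markers had 1 of 7 lower, the cilia factor gene Foxj1, also adjusted over the list alone (camera adjusted p = 0.132, and 0.035 without cortical 2). Mural and fibroblast markers had 1 of 9 lower, the collagen gene Col1a2, also adjusted over the list alone (camera adjusted p = 0.752, direction down with a median of 0.11). Of the endothelial list 2 of 11 genes were tested and 0 called, too few for a set test, and of 3 tested blood cell markers 0 were called (camera adjusted p = 0.866, direction up with a median of -0.60), both also adjusted over the list alone. Leaving the genes of these lists and of the progenitor and neuroblast list out of the count left 776 of the 802 region calls. Listed genes were only dropped from the count, without a new fit. This cannot tell how many of the other calls came from RNA of other cells.

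**Figure D4:**
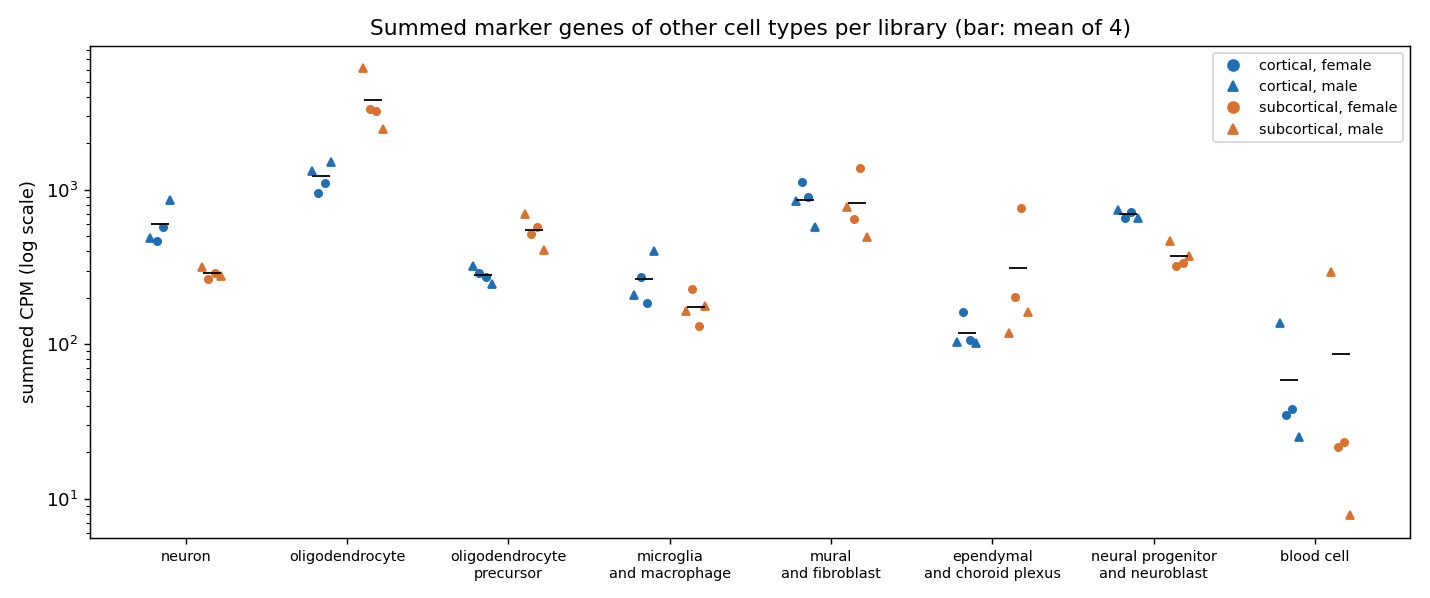
Summed CPM (log scale) of marker genes of 8 other cell types in each library (circles female, triangles male; bars are means of 4). Oligodendrocyte markers averaged 1229 CPM in cortical and 3793 CPM in subcortical libraries, and blood cell markers were highest in both libraries of mouse 1.

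The second comparison asked whether astrocytes of females and males differ, within each region and over both. The differences that were found lay almost wholly in genes of the sex chromosomes. Xist, the RNA that silences one X chromosome in females, stood at 1208 ± 265 CPM in female and 10.8 ± 5.1 CPM in male libraries (SD, n = 4 libraries from 2 mice per sex, as for the Y-linked genes here). The Y-linked genes Ddx3y (78.8 ± 17.8 CPM) and Uty (51.7 ± 10.8 CPM) were found in males (SD, n = 4), with 3 and 2 counts in all female libraries together. Their count ratios, male to female, were both 334, with 95% counting intervals of 114 to 1621 and 92.1 to 2763. Levels of these genes matched the labelled sex in 8 of 8 libraries. In cortical cells 5 of 13334 genes were called by edgeR, with Xist (log2 fold change 7.31, female minus male) and Tor3a higher in females and Ddx3y, Uty and Eif2s3y higher in males. In subcortical cells 4 were called, Xist (6.40) and the same 3 Y-linked genes. With counts summed per mouse, 5 of 13402 genes were called, Xist and the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d; Kdm5d had 0 counts in females and was at least 57.1-fold higher in males. The X-linked genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x, whose Y-linked partners are Uty, Kdm5d, Eif2s3y and Ddx3y, were not called in either region, and the whole list was not called by region (0 of 9, also adjusted over the list alone; camera adjusted p = 0.736).

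Tor3a, a torsin ATPase gene on an autosome, stood at 49.8 ± 8.9 CPM in female and 12.1 ± 2.3 CPM in male cortical libraries (SD, n = 2, edgeR adjusted p = 0.049). The call was lost without cortical 1, 2 or 4 (adjusted p = 0.125, 0.298 and 0.074), with DESeq2-type size factors in edgeR (0.055), a stricter low-count filter (0.057) and limma-voom (0.377). In subcortical cells it stood at 45.9 ± 1.7 and 53.7 ± 5.8 CPM (SD, n = 2), and the interaction, 2.27 on the log2 scale, had an edgeR adjusted p of 1.00. Eif2s3y lost its cortical call without cortical 2 (adjusted p = 0.106) and its subcortical call without subcortical 2 or 3 (0.076 and 0.165) or with the stricter filter (0.060). With limma-voom Xist alone was called in each region, and the adjusted p of the 3 Y-linked genes was at least 0.778. Single libraries also moved the counts. In cortical cells the count was 18 without cortical 1, 12 without subcortical 1, 9 without cortical 3, 8 without subcortical 4 and 3 without cortical 2. In subcortical cells it was 11 without subcortical 4 and 7 without cortical 1, cortical 2 or subcortical 1. Over both regions it was 30, 12, 12 and 13 without mouse 1, 2, 3 or 4.

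Adrenergic receptor genes did not pass the test between the sexes. Adrb1 stood at 100.7 ± 3.6 CPM in female and 91.9 ± 8.3 CPM in male cortical libraries, and at 132.0 ± 4.6 and 146.0 ± 22.5 CPM in subcortical ones (SD, n = 2). Its log2 fold changes, female minus male, were 0.14 (SE 0.27) and -0.15 with edgeR adjusted p of 1.00 each. In simulated data the test of sex in cortical cells found 8% of 2-fold and 66% of 4-fold changes, and in subcortical cells 11% and 62%. All simulated changes were in genes with a mean of at least 10 CPM, so these rates do not cover lower genes. For Adrb1 the 95% intervals were -0.42 to 0.69 in cortical and -0.70 to 0.41 in subcortical cells, and for Adra2a -0.25 to 0.82 and -0.78 to 0.29, so that a 2-fold difference lay outside them. For Adra1a and Adra1b the intervals reached a 2-fold difference, at -1.22 in cortical and -1.001 in subcortical cells for Adra1a and at 1.32 in cortical and -1.21 in subcortical cells for Adra1b. On counts summed per mouse the difference of Adrb1 was -0.01 (SE 0.20). Among the gene lists, the X and Y linked list was called in cortical cells (camera adjusted p = 0.00022; with an estimated correlation, adjusted p = 0.318). In subcortical cells 6 lists were called and 0 with an estimated correlation. These were the X and Y linked list (with an estimated correlation, adjusted p = 0.488), white matter and fibrous astrocyte markers (0.488), the Wnt pathway (0.488) and blood cell markers (0.623), all down in females, and mural and fibroblast (0.623) and ependymal and choroid plexus markers (0.581), both up. Of the members of these 6 lists, genes other than the X and Y linked ones were not called, and blood cell and ependymal markers each stood apart in a single subcortical library.

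The third comparison asked whether the difference between regions depended on sex. Lhx2 and Irx3 belonged to a region difference that was tested in each sex, as contrasts of the same fit over all 8 libraries. By edgeR 300 genes were called in females and 312 in males. Of these, 188 were called in both and all 188 moved the same way, where independent lists of those sizes would share 7.02. The 2 tests used different mice but the same filter and the same estimate of the spread per gene. Their lists were therefore not independent, and 7.02 is not a fair expectation. Of the 300 genes called in females 295 had the same direction in males, against 61.8% of all 13334 tested genes. The interaction test called 0 of 13334 genes with edgeR (smallest adjusted p 0.388), with 502 at an unadjusted p under 0.05 where 667 would be expected by chance, and 0 with DESeq2 and 0 with limma-voom. With the mouse as a block 1 gene was called, without any low-count filter 1, and 1 or 2 when a library was left out (2 without cortical 2 or subcortical 2, 1 without each of the other 6). For Adrb1 the difference between regions was -0.39 in females and -0.67 in males on the log2 scale, and the difference of 0.28 between them had an edgeR adjusted p of 1.00. In simulated data the interaction test found 1% of 2-fold and 33% of 4-fold differences, all in genes with a mean of at least 10 CPM.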

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

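The tests in this part were chosen after the results were seen, except that of the dendritic transcripts, whose bounds were set before. All 35 splits of the 8 libraries into 4 and 4 were counted. Only 1 of the 35, the real one, gave as many as 802 genes, where the highest of the others, the split by sex, gave 5. By these 35 splits a chance division of the libraries is an unlikely source of the count of region calls. The same holds for the 403 higher and 399 lower genes, since the highest other split gave 4 in a single direction and only 1 of 35 reached the real counts. For the gene lists only 1 of 35 splits, the real one, reached the 13 called lists, which is the smallest share possible here. The highest other gave 11 and 17 splits gave at least 5. Chance is therefore not excluded for their number, and single lists are less certain than single genes. These splits exchange libraries between mice. The 8 splits that part all 4 mice are too few for a share under 0.05, so splits that keep the pairing cannot exclude chance by themselves. In these the others called 0 genes and at most 6 lists.

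Samples far from the other 3 of their region were found in 26 of 304 sets of 4 values, where about 15.2 would be found by chance at 1 in 20. Blood cell markers stood apart in both libraries of mouse 1, summing to 136.5 CPM in cortical 1 (others at most 38.3) and 295.8 CPM in subcortical 1 (others at most 23.4), with Hbb-bs at 77.65 and 150.2 CPM, Hba-a1 at 59.09 and Hbb-bt at 46.6 CPM in subcortical 1. Further values of subcortical 1 were Dact2 at 4.161, Fam13c at 2.497 and Cspg5 at 542.6 CPM. In subcortical 2, Cyp26b1 was high at 185 CPM (others at most 105.9), Thbs4 stood at 0.9611 CPM and Adra1b was low at 21.14 CPM. In subcortical 3, Slc1a2 was at 5883 and Abcc9 at 35.99 CPM. In cortical 1, Aldh1a1 was at 59.79, Smad7 at 7.443 and Adra2c at 0.4962 CPM. In cortical 2, Slc1a3 was high at 6738 CPM (others at most 5544), P2ry1 at 24.25 and Dynlrb2 at 27.9 CPM, Crtc1 was low at 8.082 CPM, and ependymal and choroid plexus markers summed to 161.1 CPM. In cortical 3, Dao was at 2.102 and Pax3 at 0.2336 CPM, and in cortical 4 Vangl2 was at 149.3 CPM. For Pax3, Adra2c and Thbs4 the other 3 libraries of the region had 0 counts. Any count at all is then flagged, so these flags carry no weight in the 26.

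Ependymal and choroid plexus markers summed to 762.5 CPM in subcortical 3 (others 119 to 201.4 CPM), of which Ttr, the transthyretin gene that choroid plexus expresses strongly, made 611.9 CPM (1751 counts). Ttr was at most 23.8 CPM in the other 7 libraries; it was picked after its values were seen. A sex difference is argued against, since the subcortical library of the other female had 1.92 CPM. Choroid plexus RNA in that library may be the source: of 16 other listed choroid plexus genes 11 had counts in the other 7 libraries, and 9 of these were higher there than in the mean of the other 3 subcortical ones, with a median log2 ratio of 1.00, at percentile 99.9 of 10000 random lists matched on expression in the other 7 libraries. The most abundant of them, Enpp2 and Rarres2, stood at 124.8 and 74.8 CPM there (others at most 120.7 and 59.1), Otx2 was lower there (69.5 CPM, others 83.6 to 89.2), genes such as Slc4a5 and Folr1 had few counts (7 and 3), the sort gate is not known here, and no biological explanation beyond sex was tested.

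Oligodendrocyte markers were lower in cortical libraries, with a median log2 fold change of -1.28 over 13 genes. Fold changes are scaled for library size, so thinning all libraries to the smallest total would leave the median nearly the same in any case. It therefore cannot test the lower depth of subcortical libraries as a source. After thinning the median was -1.3 (95% interval -1.79 to -1.1). This interval is over the 13 genes, taken as independent, and does not cover variation between mice. Varying carry-over of oligodendrocyte RNA stays open. The markers moved together within regions: their deviations had a mean pairwise correlation of 0.374, at percentile 100 of 1000 matched random lists (median -0.00844). Those lists were matched on expression and not on cell type. Markers of a single cell type would exceed them whatever the source of their RNA, so this cannot tell carry-over from other sources. A difference between the tissues in these transcripts was not tested.

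Nrgn, Camk2a and Slc17a7 were higher in cortical libraries. A larger share of neuronal RNA as the whole cause is argued against, since 8 general neuron markers had a median log2 fold change of 0.563. Its 95% interval, 0.05 to 1.71, is over these genes and does not cover variation between mice. Snap25 stood at 12.9 CPM in cortical and 10.01 CPM in subcortical libraries where Nrgn stood at 195.8 and 8.73 CPM. RNA of dendrites attached to the sorted cells may add to it and stays open: 6 of 8 other dendritic transcripts could be tested, with a median of 0.858 (95% interval 0.06 to 2.15, all 6 values). The bounds set in advance, a median above 2 for it or a median under 1 with an upper limit under 2 against it, were both missed. Psd (log2 fold change 2.15, edgeR adjusted p = 0.036) went with it, though it was highest in cortical 4 (38.06 CPM, other cortical libraries 3.97 to 17.47). Ddn (6 to 44 counts per cortical library, 1 count in subcortical 1 and 0 in the others) did too. Dlgap3, Shank1 and Dlg4 had 1.915, 0.94 and 0.77, whereas Map2 and Ppp1r9b hardly moved (0.18 and 0.06). Shank3, too low to test, had counts in subcortical libraries only. Neurons that differ by region stay open as an untested difference of tissue.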

How the results depend on the processing

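Thinning all libraries to the smallest total, leaving other-cell marker genes out of the count and leaving libraries out of the list tests were chosen after the results were seen. Leaving marker genes out only drops them from the count, without a new fit. The count of 802 region genes lay between 776 and 1029 with DESeq2-type size factors, DESeq2, limma-voom, no or a stricter low-count filter, TMM factors without mitochondrial and other-cell genes, the mouse as a block, sex as a covariate, thinning or other-cell marker genes left out, and between 614 and 775 without single libraries; 792 of the 802 were shared with DESeq2 and 710 with limma-voom. It was 333 (177 higher, 156 lower) against a fold of 1.5 and 477 (251 higher, 226 lower) at an adjusted p under 0.01, both stricter by construction. Within the fit by sex and region it was 300 in females and 312 in males, with fewer libraries per group. The called genes followed over these settings held those chosen by the naming rule and some picked after the values were seen, such as Gnao1 and Malat1. Of these 108 genes, 74 kept their call under all settings, 14 lost it only against a fold of 1.5 and 18 without some library. Many were chosen in these data for a large difference or a small p, so these shares do not stand for the 802. DESeq2 called 2 adrenergic receptor genes in place of 1. The adjusted p of Adrb1 was 0.023 with DESeq2 and at most 0.23 with edgeR without single libraries. Over the other settings, which include the test against a fold of 1.5, it reached 1.00. For sex, the cortical count of 5 was 9 with DESeq2, 1 with limma-voom, 16 without a filter and 3 to 18 without single libraries. The subcortical count of 4 was 1 with limma-voom, 8 without a filter and 5 to 11 without single libraries, and that over both regions, 5, was 1 with limma-voom, 15 without a filter, 3 with the mouse as a random effect and 12 to 30 without single mice. The interaction count of 0 was 1 without a filter, 1 with the mouse as a block and 1 to 2 without single libraries. Where a single library was left in a group, it was assumed to vary like the other groups; the cause of these moves was not tested. Of the called lists, 5 of 13 by region, 0 of 1 by sex in cortical and 0 of 6 in subcortical cells passed with an estimated correlation; leaving out members that other-cell lists also hold removed no gene and so tests nothing, and members shared between the remaining lists were not left out. Genes without a call changed sign: Adra1a (0.015) was -0.047 with limma-voom, -0.015 with the block and -0.096 to 0.208 without single libraries; Esam (0.016) was -0.049 with sex as a covariate, -0.067 when thinned and -0.28 to 0.383 without single libraries. With limma-voom and the block, the region log2 fold change of Hba-a1 (-1.186) was 1.757 and 0.483, that of Hbb-bt (-0.603) 0.42 and 0.446 (0.089 with sex as a covariate), and the region log2 fold change of Hbb-bs (-0.365) 0.753 and 0.416. Without single libraries they ranged from -2.172 to 2.052, -1.554 to 2.718 and -1.058 to 1.545, each highest without subcortical 1, where they stood apart from the other subcortical libraries. The subcortical sex difference of Adrb1 ranged from -0.297 to 0.017 without single libraries; the cause was not tested. Depth limits what was seen of genes near 0 counts, such as Adra2c.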

Other observations

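Abundant genes outside the lists were looked at after the values were seen. Gnao1, the gene of the inhibitory G protein subunit Go, stood at 1341 ± 57 CPM in cortical and 168 ± 20 CPM in subcortical libraries (SD, n = 4, log2 fold change 3.00, edgeR adjusted p = 4.9e-11). Slco1c1, a thyroid hormone transporter gene, stood at 1048 ± 110 against 360 ± 51 CPM (SD, n = 4). Mgll, which encodes the lipase that degrades 2-arachidonoylglycerol, stood at 1181 ± 329 against 309 ± 32 CPM, and the membrane protein genes Tspan7 and Gpm6a at 2244 ± 291 against 604 ± 74 and 2266 ± 121 against 950 ± 59 CPM (SD, n = 4). Higher in subcortical cells were Cd81, a tetraspanin gene (1227 ± 169 against 2552 ± 247 CPM), Mmp14, a matrix metalloproteinase gene (411 ± 47 against 1007 ± 310 CPM), and Lgi1, a secreted synaptic protein gene (358 ± 49 against 879 ± 100 CPM; SD, n = 4). These 8 genes passed edgeR's adjusted p of 0.05 with and without the mouse as a block.

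Malat1, a nuclear long noncoding RNA, was the most abundant called gene outside the lists, at 31000 ± 12110 CPM in cortical and 72471 ± 38840 CPM in subcortical libraries (SD, n = 4, log2 fold change -1.23, edgeR adjusted p = 0.0045). The call was lost with DESeq2 (adjusted p = 0.101) and when tested against a fold of 1.5 (0.085). Without single libraries the log2 fold change lay between -1.52 and -0.78, the latter without subcortical 2 (adjusted p = 0.020). Among 329 groups of at least 5 tested genes that share a symbol stem, 1 was called by camera and 0 with an estimated correlation. This was the Wnt ligand family, with 3 of 6 genes lower in cortical cells and a median log2 fold change of -1.42 (camera adjusted p = 0.048; with an estimated correlation, adjusted p = 0.998). Its member Wnt5a had a log2 fold change of -1.75 (edgeR adjusted p = 0.0052).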
